A study of Mus musculus with 9 samples.

How the data were processed

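Single-cell RNA sequencing was done on dissociated tumours that grew from collagen gels seeded with KPC cells, a mouse pancreatic cancer line, and implanted into C57BL/6J mice. The labels name 3 treatments: control, immune checkpoint blockade (ICB) alone, and ICB with CA-4948 (emavusertib, an inhibitor of the kinase IRAK4). Cells were frozen, thawed and captured with the 10x Genomics GEM-X 5' v3 chemistry at a target of 20000 cells, and sequenced on a Singular Genomics G4 instrument. Each value deposited by the authors is a count of UMIs (unique molecular identifiers) per gene and barcode, and per the labels each sample is a biological replicate. Nothing else states whether the samples came from separate animals. The deposited count matrices are raw: they hold all barcodes, empty droplets included, with 33696 features and no normalisation or filter. Per the labels and the deposited lists, the other names that came with the counts are barcodes, gene identifiers and symbols. The submitters' processing notes name Cell Ranger 7.1.0 and 8.0.1, Seurat, and the mouse builds mm10 and GRCm39, without a role for any of them. Genes are therefore given by the deposited symbol, the leading ones also by identifier, with no coordinates.

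The series lists 9 samples, and count matrices of 8 were at hand. For Control replicate 3 barcode and feature names were at hand but no counts, so this sample was not analysed here. Groups follow the sample titles. The ICB + CA-4948 deposits of replicates 2 and 3 held the same cell barcodes (over 50% of the smaller set) and were merged into 1 library by the mean of their counts. This left 7 libraries: 2 Control, 3 ICB and 2 ICB + CA-4948. The merged library may hold cells of more than 1 tumour.

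Cells were called per library in the manner of Cell Ranger's OrdMag rule (barcodes above the 99th percentile of the 20000 highest barcodes, divided by 10). Barcodes with at least 500 UMIs below that limit were added when they differed from the ambient profile (barcodes of up to 100 UMIs) in a multinomial Monte Carlo test with 10000 simulations at a false discovery rate of 0.01. Called barcodes needed at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs. Doublets were removed by Scrublet score at 0.4% of barcodes per 1000 retained. Counts were log-normalised, and 2000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering at resolution 1, without integration of libraries (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). Clusters were named from fixed marker genes. A marker counted when at least 10% of a cluster's cells had a UMI of it and its mean was over 1.5-fold that of other cells. T and NK cells, fibroblasts, and macrophages and monocytes were clustered again for sub-classes.

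Counts were summed per library and class for 5 classes: malignant epithelial cells, fibroblasts, macrophages or monocytes, neutrophils and T cells. A library needed at least 20 cells of a class. Genes were tested with the edgeR 4.0.16 quasi-likelihood F test (robust, TMM normalisation, filterByExpr) in R 4.3.3, with 1 coefficient per group over all 7 libraries and a Benjamini-Hochberg adjusted p under 0.05 within a class and comparison. The 3 comparisons were ICB + CA-4948 against ICB, ICB against Control, and ICB + CA-4948 against Control. Of 30 fixed gene lists, 29 had at least 3 tested members in some class. They were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM (UMIs scaled by library size; prior count 2), with camera at an estimated correlation and fry beside it. List values are the mean difference in log2 CPM over tested members. Members were also counted past the threshold adjusted over the list alone. Cell shares are percentages of cells in named clusters and were compared by exact two-sided permutation of libraries, adjusted over classes and comparisons. Shares of single libraries have 95% Wilson intervals. The smallest p is 0.1 for 3 libraries against 2, and 0.333 for 2 against 2, so no share could reach 0.05.

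Genes are named by a fixed rule: genes past the threshold, of which there were none in edgeR; up to 2 members with the smallest unadjusted p from each list past the camera threshold; and fixed genes of the MYD88 pathway, fibroblast, antigen presentation and T cell biology. Any other named gene is said to be chosen after its values were seen. Free RNA was estimated per class by scaling the ambient profile to markers of other classes (25th percentile of their ratios). Host sex was read from Xist and Ddx3y. The gene test was tested on simulated data in which 200 genes were changed 2-fold or 4-fold, and the ambient test on simulated empty droplets.

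The marker genes, gene lists, naming rule and the following alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no expression filter, the replicate number as a block, each library left out in turn, ambient-prone genes left out (over 50% of counts), 1000 UMIs, 10% mitochondrial UMIs, no doublet removal, OrdMag barcodes alone, equal total counts, an edgeR test of cell numbers, and Leiden resolution 2. Chosen after the data were seen were the separate or single use of the merged deposits, their 2 components as samples, host sex as a covariate, subtraction of ambient counts, and the CD8 T sub-clusters alone. A genome annotation from another release was at hand and was left out, as was the third Control sample.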

Results

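Gene expression was measured in single cells of tumours grown from collagen gels seeded with KPC cells, a mouse pancreatic ductal adenocarcinoma line, in C57BL/6J mice. The mice received control treatment, immune checkpoint blockade (ICB), which releases T cells from inhibitory receptors, or ICB with CA-4948, an inhibitor of IRAK4. IRAK4 is the kinase that carries signals from toll-like and interleukin-1 receptors through the adaptor MYD88. Count matrices were analysed for 2 Control, 3 ICB and 3 ICB + CA-4948 samples, and Control replicate 3 was not analysed here. Total UMIs were 59083589 and 53007215 in Control replicates 1 and 2, 61248670, 45424305 and 59421000 in ICB replicates 1, 2 and 3, and 64361183, 51573808 and 53602843 in ICB + CA-4948 replicates 1, 2 and 3. After filters and doublet removal 65545 cells were kept.

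The ICB + CA-4948 deposits of replicates 2 and 3 were not separate libraries. They shared 14918 cell barcodes, 99.02% of the 15066 cells of the smaller deposit, and the log2 UMI totals of shared cells had a correlation of 0.99 across cells, which are not independent replicates. No other pair of deposits shared more than 49 cell barcodes. The log2 ratio of the replicate 3 total to the replicate 2 total fell into 2 groups of cells, 6465 cells around -0.153 and 8453 cells around 0.185. The groups were fitted on the 10954 cells with at least 1000 UMIs in both deposits. Cells with fewer UMIs were assigned by the same limit, and their ratios are less certain. Malignant cells made up 1.46% of the first group (95% Wilson interval 1.18 to 1.79%) and 17.9% of the second (17.1 to 18.8%). Such intervals cover counting error only. The deposits were merged and entered every comparison as 1 library, so ICB + CA-4948 entered with 2 libraries, called replicate 1 and the merged library. If the 2 groups of cells came from different tumours, the merged library is a pool of them. An SD of ICB + CA-4948 with n = 2 can then understate the spread between tumours.

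**Figure D1:**
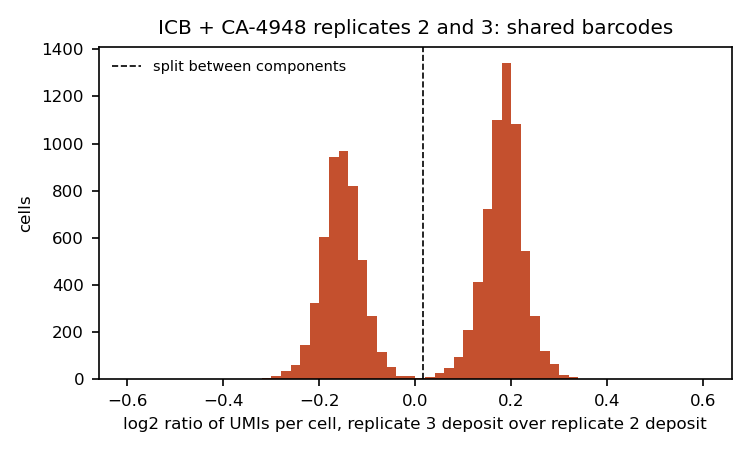
Number of cells (vertical axis) by log2 ratio of UMIs per cell between the ICB + CA-4948 replicate 3 and replicate 2 deposits (horizontal axis). Shown are the 10954 of 14918 shared barcodes with at least 1000 UMIs in both deposits. The dashed line at 0.015 splits the 2 groups of cells. The bars form separate peaks around -0.153 and 0.185.

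Host sex and free RNA differed between libraries. Xist, the RNA that silences the inactive X chromosome, stood at 333.7 to 516.8 CPM over all cells in Control replicate 2, ICB replicate 2 and both ICB + CA-4948 libraries, and at 0.09 CPM or less in Control replicate 1 and ICB replicates 1 and 3. Ddx3y, a Y-linked gene, stood at 54.8 to 131.3 CPM in the last 3 libraries. Both ICB + CA-4948 libraries were thus female, while Control and ICB held both sexes. Malignant cells had at most 6.34 CPM of Xist and 1.65 CPM of Ddx3y in every library. In Control replicate 1, 13.7% of UMIs lay in barcodes of up to 100 UMIs, which hold free RNA, against 4.89 to 7.73% in the other deposits. Free RNA was estimated at 9.77% of its T cell UMIs, against 2.72 to 5.90% elsewhere.

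Macrophages or monocytes were the most abundant class in every library. They made up 37.1% ± 7.77 (SD, n = 2) of named cells in Control, 39.3% ± 8.90 (n = 3) in ICB and 50.8% ± 0.06 (n = 2) in ICB + CA-4948. Malignant epithelial cells ranged from 9.65 to 23.6%, T cells from 4.95 to 15.7%, neutrophils from 0.965 to 17.3% and fibroblasts from 3.04 to 22.1% across libraries. Both ICB + CA-4948 libraries lay above every ICB library in the macrophage or monocyte share. The difference was within the reach of other splits of the libraries (exact permutation p = 0.2, adjusted p = 1). The groups of cells in the merged library differed in this class, with 3605 of 6042 kept cells at the lower deposit ratio and 3199 of 7986 at the higher. The separation from ICB and the SD of 0.06 thus rest on the merge. Natural killer and innate lymphoid cells made up 1.37% ± 0.13 (n = 3) in ICB and 0.76% ± 0.59 (n = 2) in Control, with every ICB library above both Control libraries (exact permutation p = 0.1, the smallest that 3 against 2 libraries can give). As a share of immune cells the 2 groups overlapped (exact permutation p = 0.3). None of 69 share tests passed an adjusted p of 0.05, which this number of libraries cannot reach, and the edgeR test of cell numbers called no class either.

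**Figure D2:**
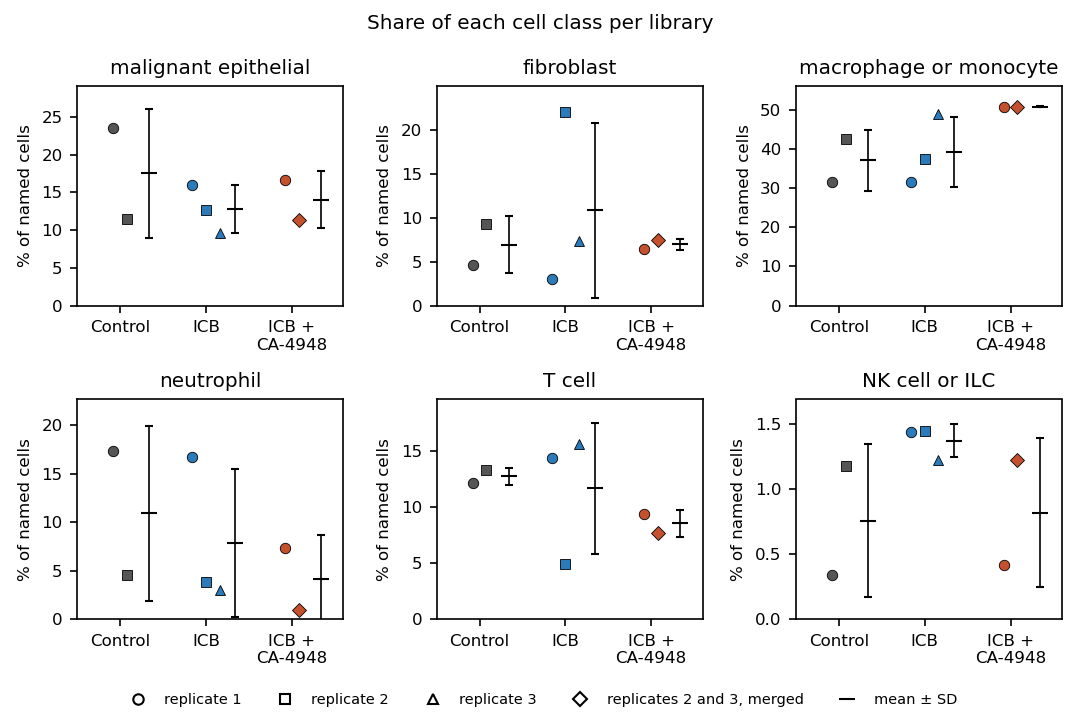
Share of 6 cell classes in percent of named cells (vertical axes) per library in Control, ICB and ICB + CA-4948 (horizontal axes); symbols mark replicates, and bars give the mean and SD, ended at 0 where they would pass below it. The macrophage or monocyte share is 50.8 and 50.9% in the ICB + CA-4948 libraries and 31.5 to 49.0% in ICB. The merged library averages 2 groups of cells that differ in this share.

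The comparison of ICB + CA-4948 with ICB asks what the IRAK4 inhibitor adds to checkpoint blockade. Genes that respond to interferon gamma, the T and NK cell cytokine that drives antigen presentation, were lower with the inhibitor in malignant cells, macrophages and neutrophils. T cells had lower levels of exhaustion and checkpoint genes, which mark T cells under lasting antigen stimulation. The NF-kB and MYD88-pathway inflammatory targets, the genes nearest to the inhibited kinase, passed the list test in none of the 5 classes. Each of these calls used camera's preset correlation, and none was kept with an estimated correlation (smallest adjusted p = 0.0916). No single gene passed in any class by edgeR, so each of these is a statement about a list.

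In malignant epithelial cells the interferon gamma response list fell, with 0 of 32 members above 0 and a mean difference of -0.61 (camera adjusted p = 1.11e-06; adjusted p = 0.754 with an estimated correlation). Its members Irf1 (ENSMUSG00000018899), an interferon-induced transcription factor, and Irgm1, an interferon-induced GTPase, stood at 132.5 ± 36.2 and 70.1 ± 15.0 CPM (SD, n = 2) against 232.6 ± 31.4 and 147.2 ± 43.8 CPM in ICB (n = 3). The type I interferon response list fell by 0.80, with 0 of 30 members above 0 (camera adjusted p = 6.94e-06; adjusted p = 0.754 with an estimated correlation). Both calls held without each library, but the size of the difference rested on single tumours. The interferon gamma difference was -0.30 without ICB replicate 2 and -1.10 without ICB replicate 3. The type I difference was -0.43 without ICB replicate 1, -0.44 without ICB replicate 2 and -1.54 without ICB replicate 3. ICB replicate 3 had an interferon gamma list level of 4.86, below both ICB + CA-4948 libraries at 5.14 and 5.29. When the merged library was split by deposit ratio, the group of lower ratio, with 88 malignant cells, stood at 3.01 and the other at 5.42. Cell cycle genes fell as a list too, with 0 of 30 members above 0 and a mean difference of -0.55 (camera adjusted p = 7.48e-11; adjusted p = 0.754 with an estimated correlation). Pbk, a mitotic kinase, stood at 9.25 ± 1.60 CPM against 17 ± 1.46. This call was lost without ICB + CA-4948 replicate 1 (-0.04, adjusted p = 0.753), and the difference was -1.08 without the merged library. Mitochondrially encoded genes, a sign of RNA quality, rose by 0.27 in these cells (camera adjusted p = 0.0113; adjusted p = 0.754 with an estimated correlation), a call lost without ICB replicate 3 (0.11, adjusted p = 0.359) and without the merged library (0.24, adjusted p = 0.358).

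In the macrophage or monocyte class the interferon gamma response list fell by 0.66, with 1 of 31 members above 0 and 8 members lower when adjusted over the list alone (camera adjusted p = 7.12e-12; adjusted p = 0.967 with an estimated correlation). The call held without each library, with the smallest difference, -0.41, without the merged library. Single libraries overlapped: the list level was 5.46 in ICB replicate 3 and 5.50 in ICB + CA-4948 replicate 1. The low level of the merged library sat in 1 of its groups of cells, at 4.55 in the group of lower deposit ratio and 6.01 in the other, beside 5.69 for ICB replicate 3 when normalised with them. Class II genes stood at 7.13 and 8.01 in these groups, and classical activation genes at 5.49 and 6.78, against 8 and 6.54 in ICB replicate 3. Mitochondrially encoded genes were lower in the first group too, at 7.76 and 9.85 in macrophages (8.69 to 9.77 in ICB), 8.30 and 9.67 in fibroblasts and 9.11 and 10.47 in malignant cells. The groups also lay in different clusters: a macrophage cluster with Retnla, Chil3 and Mrc1 held 33.7% (95% Wilson interval 32.5 to 34.9%) of the kept cells of the first group and 0.751% (0.584 to 0.966%) of the second. That cluster had 2096 cells from the merged library and 36, 277 and 161 from the ICB libraries. Ciita (ENSMUSG00000022504), the master regulator of MHC class II genes, stood at 35.5 ± 3.37 CPM (SD, n = 2) against 106.5 ± 43.8 CPM in ICB (n = 3), a log2 fold change of -1.58 (SE 0.36, edgeR adjusted p = 0.873). The MHC class II presentation list fell by 0.41, with 0 of 14 members above 0 and 3 lower when adjusted over the list alone (camera adjusted p = 0.000539; adjusted p = 0.967 with an estimated correlation). H2-DMb1, which helps load peptides onto class II molecules, stood at 80.5 ± 8.53 CPM against 160.8 ± 33.2, and H2-Ab1, a class II chain, had a log2 fold change of -0.21. Without ICB replicate 1 the class II call was lost (-0.21, adjusted p = 0.106), as it was without the merged library (-0.18, adjusted p = 0.278). It was -0.66 without ICB + CA-4948 replicate 1. The classically activated macrophage list fell by 0.24, with 4 of 19 members above 0 (camera adjusted p = 0.00278; adjusted p = 0.967 with an estimated correlation), a call lost without ICB replicate 1 (adjusted p = 0.0677) and without the merged library (adjusted p = 0.17). Cd86, a costimulatory ligand for T cells, stood at 681.2 ± 34.8 CPM against 1168.8 ± 117.3.

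In neutrophils the interferon gamma response list fell by 0.96, with 1 of 21 members above 0 and 10 members lower when adjusted over the list alone (camera adjusted p = 1.42e-09; adjusted p = 0.845 with an estimated correlation). The neutrophil difference was -0.62 without ICB replicate 2, and the call held without each library. Cd274, which encodes the checkpoint ligand PD-L1, stood at 402.9 ± 30.4 CPM (SD, n = 2) against 877.4 ± 133.0 CPM in ICB (n = 3). The merged library held 129 neutrophils, the fewest of any library. Against the direction of the interferon gamma list, MHC class II presentation genes, which macrophages express, rose by 1.20 (camera adjusted p = 0.00983), and the list of antigen-presenting fibroblasts rose by 1.02 (0.0246). Stress genes fell by 0.57 (camera adjusted p = 0.000246), and none of these was kept with an estimated correlation (adjusted p = 0.845). The class II level was 8.58 in the merged library and 6.22 to 7.60 in ICB. By deposit ratio the groups of the merged library stood at 5.54 (lower ratio, 42 neutrophils) and 8.94 (87 neutrophils). ICB stood at 6.26 to 7.62 when normalised with them, so the high level lay in 1 group as split. The split was fitted on cells with at least 1000 UMIs in both deposits, which 23 of the 129 neutrophils had. Most neutrophils were thus assigned by a limit fitted on cells with more UMIs. The class II call was lost without the merged library (0.42) and without ICB replicate 3 (0.97, adjusted p = 0.0888). The call of the fibroblast list was lost without the merged library (0.49, adjusted p = 0.721) and without ICB replicate 2 (0.70, adjusted p = 0.107). The stress call was lost without ICB + CA-4948 replicate 1 (adjusted p = 0.266).

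In T cells the exhaustion and checkpoint list fell by 0.51, with 2 of 21 members above 0 and 3 lower when adjusted over the list alone (camera adjusted p = 2.05e-07; adjusted p = 0.0916 with an estimated correlation). The list levels were 7.45 and 7.29 in the ICB + CA-4948 libraries and 7.84 to 7.93 in ICB, and the call held without each library. When the merged library was split by deposit ratio, its groups stood at 7.07 (lower ratio) and 7.64, so the low level lay mostly in the first. Mitochondrially encoded genes of T cells were also lowest in that group, at 8.01, against 9.57 in the other and 8.76 to 9.50 in ICB. Tox (ENSMUSG00000041272), a transcription factor of the exhaustion programme, stood at 646.0 ± 2.78 CPM (SD, n = 2) against 1631.1 ± 300.8 CPM (n = 3), a log2 fold change of -1.33 (SE 0.34, edgeR adjusted p = 0.778). Cd101, a marker of terminally exhausted cells, stood at 66.9 ± 3.58 CPM against 131.3 ± 23.7, and Lag3, an inhibitory receptor, at 108.9 ± 37.0 against 184.5 ± 17.7. The receptors Pdcd1 (PD-1) and Ctla4 had log2 fold changes of -0.05 and 0.06, and Tcf7, a factor of stem-like T cells, one of 0.16. The cytotoxic effector list fell by 0.34 on average, with 9 of 22 members above 0 (camera adjusted p = 0.00539; adjusted p = 0.656 with an estimated correlation), a call lost without ICB replicate 2 (-0.17, adjusted p = 0.0547) and without ICB + CA-4948 replicate 1 (-0.23, adjusted p = 0.0572). Its members Ccl3 and Ccl4, chemokines of activated CD8 T cells, stood at 73.9 ± 19 and 336.6 ± 64.4 CPM against 288.2 ± 84.0 and 1073.9 ± 386.1 in ICB. The log2 fold change of Ccl3 was -1.94 (SE 0.28, edgeR adjusted p = 0.0903). Acinar enzyme genes, which T cells do not express, rose by 0.85 with 5 of 6 members above 0 (camera adjusted p = 0.0217; adjusted p = 0.656 with an estimated correlation), a call lost without ICB replicate 1 (adjusted p = 0.0705) and without ICB replicate 3 (adjusted p = 0.139). Cd4 had a log2 fold change of 0.98 and Cd8a one of -0.45. CD4 T cells that were not regulatory made up 9.08% ± 2.24 (n = 2) of T and NK cells against 3.37% ± 1.99 in ICB (n = 3, exact permutation p = 0.1, the smallest possible). This p is unadjusted and comes from a family of 45 sub-class share tests, none of which can reach 0.05.

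Fibroblasts, the cells in which the series addresses MYD88 signalling, had lower type I interferon response genes with the inhibitor, a list difference of -0.49 with 1 of 28 members above 0 (camera adjusted p = 0.00165; adjusted p = 0.7 with an estimated correlation). The MHC class II presentation list rose by 0.67, with 9 of 10 members above 0 (camera adjusted p = 0.00165; adjusted p = 0.7 with an estimated correlation). Split by deposit ratio, the merged library stood at 3.27 (lower ratio) and 4.50 for class II, beside 3.18 to 4.62 in ICB. Genes of neutrophil activation and myeloid suppression, which mark other cell types, rose by 0.78 too (13 of 17 above 0; camera adjusted p = 0.00525; adjusted p = 0.7 with an estimated correlation). That call was lost without ICB replicate 2 (adjusted p = 0.528) or ICB + CA-4948 replicate 1. In the fibroblast class the type I call was lost without ICB replicate 1 (adjusted p = 0.406), ICB replicate 2 (0.0764) or ICB + CA-4948 replicate 1 (0.051), and the difference was -0.94 without ICB replicate 3. The class II call was lost without ICB replicate 2 (adjusted p = 0.0764), ICB replicate 3 (0.0725), ICB + CA-4948 replicate 1 (0.0708) or the merged library (0.0797), and the difference was 1.15 without ICB replicate 1. Other fibroblast calls were the lists of antigen-presenting fibroblasts (0.51, camera adjusted p = 0.0282), which holds class II genes, of myofibroblasts (0.38, camera adjusted p = 0.0323) and of sex-linked genes (-2.06, camera adjusted p = 0.0345), the last in a group with female hosts alone. None of these was kept with an estimated correlation (adjusted p = 0.7). Without ICB + CA-4948 replicate 1 the 3 were lost, at 0.18, 0.11 and -1.60 (adjusted p = 0.788, 0.62 and 0.133). Irak4 and Myd88 had log2 fold changes of -0.04 (SE 0.23) and 0.16 (SE 0.28). The MYD88-driven cytokine genes Il6 and Cxcl1, marks of inflammatory fibroblasts, had log2 fold changes of 0.04 (SE 0.76) and 0.18 (SE 0.69), and Il6 stood at 554.8 ± 553.3 CPM (SD, n = 2) against 537.8 ± 219.4 (n = 3).

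By edgeR 0 genes passed in each of the 5 classes for ICB + CA-4948 against ICB. At an unadjusted p under 0.05 there were 362 of 16091 tested genes in malignant cells, 225 of 13828 in fibroblasts and 729 of 13208 in macrophages. Neutrophils had 303 of 5413 and T cells 406 of 9788. DESeq2 called 0, 0, 18, 0 and 8 in these classes in this order. With no effect a share of 0.05 of tested genes is expected under that unadjusted p. Malignant cells, fibroblasts and T cells lay below this share, and macrophages and neutrophils near it. Camera called 30 of 142 list tests, 13 higher and 17 lower, of which 5 held without each library and 25 were lost without some library. None passed with an estimated correlation, where the smallest adjusted p was 0.0916, or by fry, where it was 0.0537. For 2 called lists the summaries differed in sign. The neutrophil activation list of malignant cells was called higher (camera adjusted p = 0.0273) with a median log2 fold change of 0.30 and a mean of -0.17, and was lost without ICB replicate 2 (adjusted p = 0.412), ICB replicate 3 (0.0532), ICB + CA-4948 replicate 1 (0.0528) or the merged library (0.456). The chemokine list of T cells was called lower (camera adjusted p = 0.0423) with a median of 0.02 and a mean of -0.56, and was lost without Control replicate 1 (adjusted p = 0.132), Control replicate 2 (0.118), ICB replicate 2 (0.0516) or the merged library (0.847). Leaving out 1 library gave edgeR a few genes, chosen after their values were seen: Ciita, Serpinb10 and Spon1 in macrophages and Klrh1 in T cells and AW011738 in neutrophils without ICB replicate 3, Igkc in fibroblasts and Camp, Cybb, Ngp and Wfdc21 in neutrophils without ICB + CA-4948 replicate 1, and Camp, Ngp and Rap1gap2 in neutrophils and Poln in T cells without the merged library. In simulated data of this comparison edgeR recovered 6 to 31% of genes changed 2-fold and 71 to 97% of genes changed 4-fold, depending on the class. Single genes with 2-fold changes were thus mostly out of reach at this number of libraries. In the same simulations 5.3 to 12.7% of the calls were false, above the aim of 0.05.

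**Figure D3:**
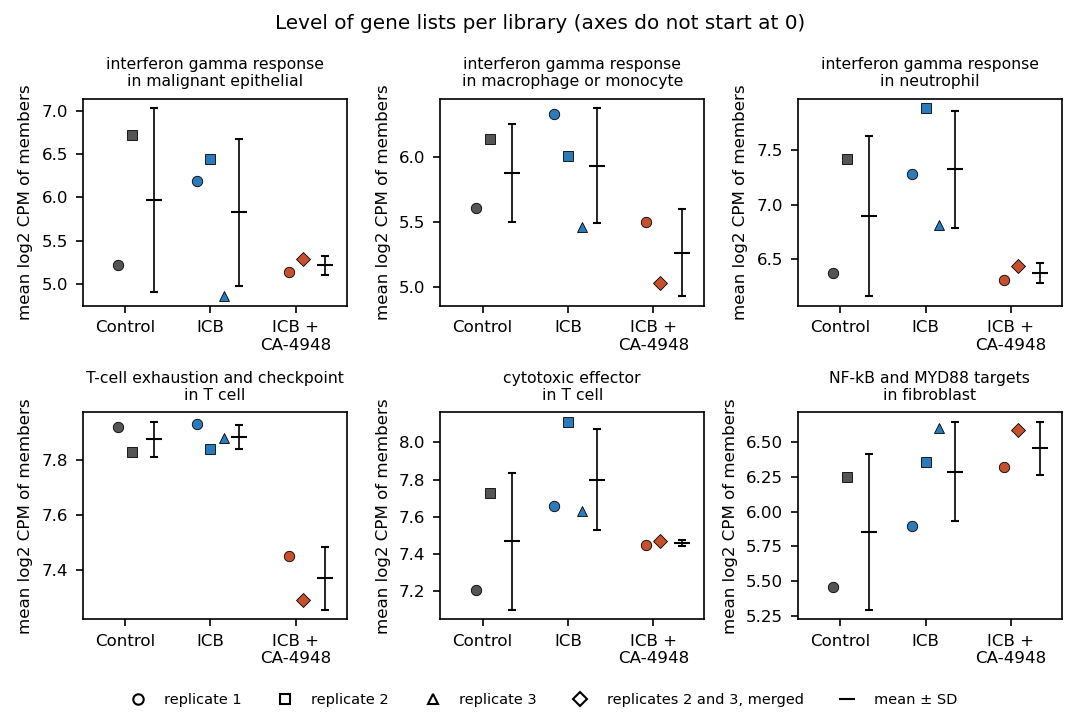
Mean log2 CPM of the members of 4 gene lists (vertical axes, which do not start at 0) in the class named above each panel, per library in Control, ICB and ICB + CA-4948 (horizontal axes); symbols mark replicates and bars the mean and SD. The T cell exhaustion list is at 7.29 and 7.45 in ICB + CA-4948 and at 7.83 to 7.93 in the other libraries, and the interferon gamma list of malignant cells is lowest in ICB replicate 3 at 4.86.

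The comparison of ICB with Control asks what checkpoint blockade does alone. Fibroblasts had higher NF-kB and MYD88-pathway inflammatory targets and lower cell cycle genes, neutrophils had higher interferon gamma response genes, and T cells had higher cytotoxic effector genes. Malignant cells had no list past the test, and none of these calls was kept with an estimated correlation (smallest adjusted p = 0.6). The inflammatory, interferon gamma and cytotoxic calls were lost without Control replicate 1. That library had the most free RNA in T cells and macrophages, but not in fibroblasts (13.6%, against 12.6 to 19.1% elsewhere) or neutrophils (10.2%, against 10.4% in ICB replicate 1). Transcripts of other cell types were lower in ICB macrophages, T cells, fibroblasts and neutrophils in the same comparison.

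In fibroblasts the NF-kB and MYD88-pathway list rose by 0.43, with 25 of 32 members above 0 (camera adjusted p = 5.43e-05; adjusted p = 0.746 with an estimated correlation). The NF-kB subunits Nfkb1 and Relb stood at 1683.7 ± 580.2 and 72.0 ± 16.3 CPM (SD, n = 3) against 746.2 ± 223.5 and 43.1 ± 5.39 CPM in Control (n = 2). Il6 had a log2 fold change of 0.66 (SE 0.77). The fibroblast difference was 0.04 without Control replicate 1 (adjusted p = 0.251), 0.82 without Control replicate 2 and 0.27 without ICB replicate 3. The dissociation and thaw stress list, immediate early and heat shock genes that tissue handling induces, rose by 0.31 in the same cells, with 21 of 24 members above 0 (camera adjusted p = 9.94e-05; adjusted p = 0.746 with an estimated correlation). This call too was lost without Control replicate 1 (0.10, adjusted p = 0.251), and the difference was 0.53 without Control replicate 2. Cell cycle genes fell by 0.59 with 4 of 30 members above 0 (camera adjusted p = 2.19e-07; adjusted p = 0.746 with an estimated correlation). That call held without each library, at -0.26 without Control replicate 1, -0.92 without Control replicate 2 and -0.31 without ICB replicate 3. Mitochondrially encoded genes rose by 0.17 and hypoxia genes by 0.28 in these cells (camera adjusted p = 0.0212 and 0.0354; 0.746 and 0.82 with an estimated correlation). The mitochondrial call was lost without Control replicate 2 (0.11, adjusted p = 0.383) or ICB replicate 2 (0.11, 0.252), and the hypoxia call without Control replicate 2 (-0.18, 0.527), ICB replicate 1 (0.15, 0.307) or ICB replicate 3 (-0.03, 0.879). The mitotic cyclin Ccnb2 stood at 10.9 ± 3.54 CPM against 21.5 ± 9.89. Type I interferon response genes of fibroblasts rose by 0.39, with 24 of 28 members above 0 (camera adjusted p = 0.0212; adjusted p = 0.82 with an estimated correlation). That direction depended on the library. The difference was -0.43 without Control replicate 1 (adjusted p = 0.00879, a call the other way), 1.27 without Control replicate 2, 0.02 without ICB replicate 1 (adjusted p = 0.921), 0.22 without ICB replicate 2 (adjusted p = 0.252) and 0.84 without ICB replicate 3. The interferon gamma list of fibroblasts rose by 0.34 (23 of 27 above 0; camera adjusted p = 0.0212; 0.82 with an estimated correlation), a call lost without Control replicate 1 (-0.29, adjusted p = 0.109) or ICB replicate 1 (-0.06, 0.514). Genes of myofibroblasts fell by 0.53 (7 of 27 above 0; camera adjusted p = 0.00863; 0.746 with an estimated correlation), a call lost without Control replicate 1 (-0.12, adjusted p = 0.987) or ICB replicate 2 (-0.26, 0.541).

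Neutrophils had an interferon gamma response list that rose by 0.43, with 18 of 21 members above 0 (camera adjusted p = 0.00023; adjusted p = 0.792 with an estimated correlation). Gbp5, an interferon-induced guanylate-binding protein, stood at 155.5 ± 17 CPM (SD, n = 3) against 78.0 ± 32.1 CPM (n = 2). In the neutrophil class the difference was -0.12 without Control replicate 1 (adjusted p = 0.96), 0.09 without ICB replicate 2 (adjusted p = 0.171), 0.82 without Control replicate 2, 0.71 without ICB replicate 3 and 0.20 without the merged ICB + CA-4948 library, which shares the fit. NF-kB and MYD88-pathway targets of neutrophils rose by 0.23, with 21 of 27 members above 0 (camera adjusted p = 0.00785; adjusted p = 0.792 with an estimated correlation), a call lost without Control replicate 1 (0.07, adjusted p = 0.349) and without ICB replicate 3 (adjusted p = 0.315).

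In T cells the cytotoxic effector list rose by 0.33, with 17 of 22 members above 0 (camera adjusted p = 0.00436; adjusted p = 0.6 with an estimated correlation). Gzmk, a granzyme of effector memory CD8 T cells, and Prf1, the pore-forming protein of killer cells, stood at 143.7 ± 73.7 and 242.8 ± 59.5 CPM (SD, n = 3) against 53.9 ± 18 and 148.5 ± 51.4 CPM (n = 2). Within the CD8 T sub-clusters the cytotoxic call was lost (0.15, adjusted p = 0.432). Pdcd1 and Cd8a had log2 fold changes of -0.08 and 0.24. Type I interferon response genes rose by 0.35 with 18 of 20 members above 0 (camera adjusted p = 0.00394; adjusted p = 0.718 with an estimated correlation). The T cell cytotoxic difference was 0.08 without Control replicate 1 (adjusted p = 0.532), 0.16 without ICB replicate 2 (adjusted p = 0.221) and 0.58 without Control replicate 2. The type I difference was -0.17 without Control replicate 1 (adjusted p = 0.375) and 0.73 without Control replicate 2.

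Transcripts that T cells, macrophages, fibroblasts and neutrophils should lack were lower in ICB. The epithelial differentiation list differed by -1.24 in T cells (2 of 8 members above 0; camera adjusted p = 8.2e-06; adjusted p = 0.6 with an estimated correlation) and by -1.36 in the macrophage or monocyte class (2 of 14 above 0; camera adjusted p = 3.05e-11; adjusted p = 0.834 with an estimated correlation). The keratin gene Krt8 (ENSMUSG00000049382) stood at 8.44 ± 0.841 CPM (SD, n = 3) in ICB T cells against 47.7 ± 22.8 CPM (n = 2). Collagen and extracellular matrix genes, products of fibroblasts, differed by -1.04 in T cells (0 of 12 above 0; camera adjusted p = 1.88e-05; adjusted p = 0.6 with an estimated correlation) and by -0.79 in macrophages (4 of 29 above 0; camera adjusted p = 6.88e-10; adjusted p = 0.834 with an estimated correlation). Acinar enzyme genes, from the normal pancreas, differed by -1.38 in T cells (0 of 6 above 0; camera adjusted p = 8.2e-06; adjusted p = 0.6 with an estimated correlation), and mitochondrially encoded genes by -0.62 (0 of 13 above 0; camera adjusted p = 1.49e-05; adjusted p = 0.6 with an estimated correlation). Without Control replicate 1 the T cell differences were -0.60 for epithelial genes (adjusted p = 0.083), -0.28 for collagen genes (0.375) and -0.16 for mitochondrial genes (0.375), and those of macrophages, still called, were -0.89 and -0.45. The acinar difference of T cells was -0.78 without Control replicate 2 (adjusted p = 0.071) and -2.12 without Control replicate 1. Without Control replicate 2 the collagen and mitochondrial differences of T cells were -2.01 and -1.09. Epithelial genes also differed by -0.73 in fibroblasts (camera adjusted p = 0.00471; 0.746 with an estimated correlation) and by -1.17 in neutrophils (0.018; 0.792), and collagen genes by -0.94 in neutrophils (0.0136; 0.792). These 3 calls were lost without Control replicate 1 (adjusted p = 0.067, 0.147 and 0.284), and the fibroblast one also without ICB replicate 2 (0.135). With the ambient expectation subtracted, the macrophage calls were lost (adjusted p = 0.8 for epithelial and 0.879 for collagen genes), and the T cell epithelial list was called in the opposite direction (0.77, adjusted p = 0.038).

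By edgeR 0 genes passed in each class for ICB against Control. At an unadjusted p under 0.05 there were 392 of 16091 tested genes in malignant cells, 288 of 13828 in fibroblasts and 198 of 13208 in macrophages. Neutrophils had 309 of 5413 and T cells 295 of 9788. DESeq2 called 7, 0, 1, 1 and 1 in these classes in this order. With no effect a share of 0.05 of tested genes is expected under that unadjusted p. All classes but neutrophils lay below this share. The single DESeq2 genes, chosen after their values were seen, were Sprr1a in macrophages (log2 fold change -2.84), Gm34455 in neutrophils (3.15) and Krt8 in T cells (-2.51). Camera called 27 of 142 list tests, 12 higher and 15 lower. The 3 that held without each library were the fibroblast cell cycle list and the macrophage epithelial and collagen lists. Of the rest, 24 were lost without some library, and none passed with an estimated correlation (smallest adjusted p = 0.6) or by fry (0.627). Leaving out 1 library gave edgeR Ins2 in fibroblasts and Il4 in neutrophils without Control replicate 1, and Ecrg4 in fibroblasts, 9 genes in neutrophils and 11 in T cells without Control replicate 2; the named ones were chosen after their values were seen. Irak4 (ENSMUSG00000059883) in malignant cells had a log2 fold change of -0.60 (SE 0.22, edgeR adjusted p = 0.999).

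The comparison of ICB + CA-4948 with Control gives the combined treatment and shares libraries with both comparisons above, so its calls are not independent of theirs. Interferon gamma response genes were lower than in Control in malignant cells, macrophages and neutrophils, exhaustion genes were lower in T cells, fibroblasts had higher NF-kB and MYD88-pathway targets, and neutrophils had lower stress genes. None of its list calls held without each library or with an estimated correlation (smallest adjusted p = 0.3). Epithelial and collagen genes were lower in macrophages and T cells here too, and mitochondrially encoded genes in T cells.

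In malignant epithelial cells the interferon gamma response list fell by 0.76, with 0 of 32 members above 0 (camera adjusted p = 0.00013; adjusted p = 0.764 with an estimated correlation), and in the macrophage or monocyte class by 0.60, with 2 of 31 above 0 (camera adjusted p = 1.95e-06; adjusted p = 0.886 with an estimated correlation). Ciita in macrophages stood at 35.5 ± 3.37 CPM (SD, n = 2) against 107.6 ± 6.56 CPM in Control (n = 2). The malignant difference was 0.00 without Control replicate 2 (adjusted p = 0.901) and -1.51 without Control replicate 1. The macrophage call was lost without Control replicate 2 (-0.33, adjusted p = 0.0956) and without the merged library (-0.39, adjusted p = 0.0641). Macrophages also had lower epithelial genes (-1.20, camera adjusted p = 0.000348) and collagen genes (-0.88, camera adjusted p = 1.87e-05), neither kept with an estimated correlation (adjusted p = 0.886) or without the merged library (adjusted p = 0.259 and 0.0641). Mitochondrially encoded genes of malignant cells rose by 0.23 (camera adjusted p = 0.0479; adjusted p = 0.764 with an estimated correlation), a call lost without Control replicate 2 (0.11, adjusted p = 0.565), ICB replicate 2 (0.052) or the merged library (0.294). Igfbp3, a binding protein of insulin-like growth factors, stood at 371.8 ± 235.6 CPM against 81.8 ± 5.60 in malignant cells.

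In T cells the exhaustion and checkpoint list fell by 0.50, with 5 of 21 members above 0 and 4 lower when adjusted over the list alone (camera adjusted p = 0.000462; adjusted p = 0.3 with an estimated correlation). The call was lost without the merged library (-0.42, adjusted p = 0.0707). Tox stood at 646.0 ± 2.78 CPM (SD, n = 2) against 2421.3 ± 1414.0 CPM (n = 2), a log2 fold change of -1.91 (SE 0.37, edgeR adjusted p = 0.143). The Control libraries stood far apart for Tox, at 3421.1 CPM in replicate 1 and 1421.4 CPM in replicate 2. Entpd1, which encodes the exhaustion marker CD39, stood at 125.9 ± 3.92 CPM against 278.3 ± 96.1. Markers of other cells and of RNA quality moved with it: epithelial genes differed by -0.96 (camera adjusted p = 0.00977), collagen genes by -1.32 (0.000462) and mitochondrially encoded genes by -0.58 (0.00874), none kept with an estimated correlation (adjusted p = 0.832). Without Control replicate 1 these were lost (adjusted p = 0.426, 0.0603 and 0.615). Unfolded protein response genes of T cells rose by 0.47, with 15 of 16 members above 0 (camera adjusted p = 0.00145; adjusted p = 0.832 with an estimated correlation). That T cell call was lost without Control replicate 1 (0.22, adjusted p = 0.189), and the difference was 0.71 without Control replicate 2.

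In fibroblasts the NF-kB and MYD88-pathway list rose by 0.60, with 27 of 32 members above 0 (camera adjusted p = 1.72e-05; adjusted p = 0.51 with an estimated correlation), and Nfkb1 stood at 1981.1 ± 214.0 CPM (SD, n = 2) against 746.2 ± 223.5 CPM (n = 2). The fibroblast difference was 0.20 without Control replicate 1 (adjusted p = 0.0567), 0.47 without the merged library (adjusted p = 0.103) and 0.98 without Control replicate 2. Stress genes rose by 0.38 in the same cells, with 20 of 24 above 0 (camera adjusted p = 4.75e-05; adjusted p = 0.51 with an estimated correlation), a call lost without Control replicate 1 (0.16, adjusted p = 0.0567) and without the merged library (0.19, adjusted p = 0.125), with 0.59 without Control replicate 2. Markers of other cell types and of RNA quality rose with them in fibroblasts. The differences were 0.57 for alternatively activated macrophage genes (camera adjusted p = 0.0284), 0.52 for classically activated macrophage genes (0.0409), 0.65 for neutrophil activation (0.0223), 0.60 for MHC class II (0.0181) and 0.31 for mitochondrially encoded genes (0.000715). None was kept with an estimated correlation (adjusted p = 0.51). Without Control replicate 2 all 5 were lost, at 0.60, 0.68, 0.22, 0.50 and 0.25 (adjusted p = 0.0926, 0.0687, 0.466, 0.217 and 0.0926). In neutrophils the stress list moved the other way and fell by 0.77, with 1 of 21 members above 0 and 5 lower when adjusted over the list alone (camera adjusted p = 8.32e-06; adjusted p = 0.875 with an estimated correlation). The neutrophil call was lost without ICB + CA-4948 replicate 1 (-0.44, adjusted p = 0.0629), and the difference was -0.32 without Control replicate 1. The interferon gamma list of neutrophils fell by 0.53, with 1 of 21 members above 0 (camera adjusted p = 0.0404; adjusted p = 0.875 with an estimated correlation), a call lost without Control replicate 2 (-0.13, adjusted p = 0.659) and without ICB + CA-4948 replicate 1 (-0.53, adjusted p = 0.107). Zfp36, an mRNA decay factor induced by stimulation, stood at 936.0 ± 527.5 CPM in neutrophils against 3212.3 ± 1173.8.

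By edgeR 0 genes passed in each class for ICB + CA-4948 against Control. At an unadjusted p under 0.05 there were 814 of 16091 tested genes in malignant cells, 450 of 13828 in fibroblasts and 1127 of 13208 in macrophages. Neutrophils had 450 of 5413 and T cells 967 of 9788. DESeq2 called 8, 0, 32, 3 and 55 in these classes in this order. With no effect a share of 0.05 of tested genes is expected under that unadjusted p. Fibroblasts lay below this share, malignant cells near it and the other classes above it. The 3 DESeq2 genes of neutrophils, chosen after their values were seen, were Ankrd22 (log2 fold change 3.33), P2ry14 (-2.10) and Zfp36 (-1.76). Without Control replicate 2 edgeR itself called 168 genes in T cells and 10 in neutrophils. Other single libraries gave few, chosen after their values were seen: Ins2 in fibroblasts and Il4 in neutrophils without Control replicate 1, Dach1 in macrophages without ICB replicate 1, Klrh1, Maf and Map2 in T cells without ICB replicate 3, Igkc in fibroblasts and Camp, Cybb, Ngp and Wfdc21 in neutrophils without ICB + CA-4948 replicate 1, and Camp and Ngp in neutrophils without the merged library. Camera called 33 of 142 list tests, 14 higher and 19 lower, all lost without some library, and none passed with an estimated correlation (smallest adjusted p = 0.3) or by fry (0.112).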

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

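The tests of the merged deposits, of host sex and of the spread between tumours, and the use of the estimated correlation to weigh the treatment, were chosen after the results were seen; ambient subtraction and the CD8 T sub-clusters were added after the data were seen, and the sex comparison of cell shares was not planned.

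The ICB against Control difference in cell shares had opposite signs in male and female hosts for some classes. The ICB less Control difference was taken from ICB replicates 1 and 3 against Control replicate 1 (male) and from ICB replicate 2 against Control replicate 2 (female). Control replicate 2 was called female by Xist but also had 8.23 CPM of Ddx3y over all cells, against 0.03 CPM in ICB replicate 2. The female side of each sex analysis thus rests on a Control library with some Y-linked signal. In 7 of 14 classes both male differences had 1 sign and the female difference the other, where chance gives 33.3% for a single class. The classes are not independent, since shares of 1 library constrain each other and all male differences use Control replicate 1. The count therefore cannot tell an effect of sex from single libraries that stand apart. In macrophages (male mean 8.63, female -5.25), endothelial cells (-0.09, 1.29) and pericytes or smooth muscle (-0.03, 0.22) the male mean opposed the female value too, but the male differences did not agree in sign, so they are not counted. For the counted classes the female less male difference, in percentage points of named cells, was -11.19 for T cells, 11.93 for malignant cells, -4.93 for B cells, -2.07 for conventional dendritic cells, -0.77 for mature dendritic cells, -0.51 for plasma cells and -0.40 for plasmacytoid dendritic cells. These differences were not tested, since each female value rests on 1 pair of libraries. A sex by ICB interaction on genes gave 0 genes by edgeR in each of 5 classes, and no other tool was run for it. At an unadjusted p under 0.05 there were 247 of 16091 tested genes in malignant cells, 561 of 13828 in fibroblasts and 623 of 13208 in macrophages. Neutrophils had 213 of 5413 and T cells 1052 of 9788. With no effect a share of 0.05 is expected there. Only T cells exceeded it, in a fit where Control had 1 library of each sex.

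The ICB + CA-4948 deposits of replicates 2 and 3 held the same cell barcodes. A single library counted from 2 sequencing runs would give 1 peak in the log2 ratio of the totals per cell, but the Bayesian information criterion of 1 normal distribution exceeded that of 2 by 16056.7, which argues against it. If reads of 2 libraries were present in both deposits in different proportions, cells of the 2 peaks would come from different tumours, and their malignant shares differed by 16.47 percentage points. A candidate explanation is therefore a mixture of reads from 2 tumours in both deposits, at a step before the matrices were made; no biological explanation was tested.

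T cells of ICB + CA-4948 tumours had lower exhaustion and checkpoint genes than those of ICB tumours. Free RNA is argued against, since the list stayed past the threshold with the ambient expectation subtracted (camera adjusted p = 9.15e-07). The same subtraction reversed the epithelial list of T cells for ICB against Control, so its scale is uncertain. A shift between CD8 and other T cells is argued against too (camera adjusted p = 7.05e-09 within the CD8 T sub-clusters). With sex as a covariate the call was kept (camera adjusted p = 0.000375). Both ICB + CA-4948 libraries were female, however, and in ICB only replicate 2 was. The design can hardly separate sex from treatment, so host sex stays open. Every ICB + CA-4948 library lay below every ICB library, which is what an effect of the added inhibitor needs, but the adjusted p was 0.0916 with an estimated correlation. With 2 libraries on one side, an effect of the inhibitor cannot be told apart from genes of 1 programme that vary together between tumours. Neither RNA quality nor a shift between states of CD8 T cells was tested as a cause, and both stay open: at the finer clustering a cluster with Xcl1 and Prf1 held 647, 96 and 354 cells of the ICB libraries and 184 and 156 of the ICB + CA-4948 libraries, and another with Ctsw and Cxcr6 held 319, 79 and 555 against 380 and 681.

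Interferon gamma response genes were lower in malignant cells and macrophages of ICB + CA-4948 tumours than of ICB tumours. Free RNA is argued against in macrophages (camera adjusted p = 2.16e-12 with the ambient expectation subtracted). With sex as a covariate the macrophage call was kept (camera adjusted p = 4.82e-13), but host sex stays open for the reason given for T cells. No call was kept with an estimated correlation (adjusted p = 0.967 in macrophages and 0.754 in malignant cells). The spread between tumours stays open: in malignant cells the lowest ICB library less the highest ICB + CA-4948 library was -0.43 in mean log2 CPM, so 1 ICB library lay below both ICB + CA-4948 libraries, although 1 of the 2 groups of cells in the merged library lay lower still (3.01, against 4.87 for that ICB library). In macrophages these groups stood at 4.55 and 6.01 and lay in different clusters, and neither a shift between macrophage states nor RNA quality was tested. Differences in inflammation between single tumours could therefore give the pattern without an effect of the inhibitor, which was not tested apart from them.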

How the results depend on the processing

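The use of the merged deposits as separate samples or alone, their 2 components as samples, host sex as a covariate, the subtraction of ambient counts and the CD8 T sub-clusters alone were chosen after the data were seen; the other alternatives were planned. With 2 or 3 libraries per group, tests without 1 library often left a group with a lone sample, which was then assumed to vary like the other groups. Among single list results under alternatives, 751 kept direction and side of the threshold, 425 fell short of the threshold and 2 reversed. No named gene passed in the main fit. Of their results under alternatives 7091 did not pass the threshold either and 81 newly passed. None of 1065 share results newly passed, in a design in which no share can pass the exact test. For named genes and shares only the side of the threshold was compared, not the direction, which may have changed. The gene counts stayed at 0 in every class and comparison with DESeq2 size factors, at least 1000 UMIs, at most 10% mitochondrial UMIs, no doublet removal, ambient-prone genes left out, either merged deposit alone, the 2 components as samples, sex as a covariate and ambient counts subtracted. OrdMag barcodes alone gave no value for neutrophils. For each result below that changed, the cause was not tested.

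The main count of genes was 0 in each class and comparison. For ICB against Control, ICB + CA-4948 against ICB and ICB + CA-4948 against Control, in this order, the DESeq2 Wald test gave 7, 0 and 8 genes in malignant cells, 1, 18 and 32 in macrophages, 1, 0 and 3 in neutrophils and 1, 8 and 55 in T cells. Without an expression filter the counts were 0, 0 and 1 in malignant cells (Serpinc1, chosen after its values were seen), 87, 417 and 570 in macrophages, 19, 7 and 42 in neutrophils and 43, 58 and 242 in T cells. At equal total counts neutrophils had 1 gene for ICB + CA-4948 against ICB (Tmsb10) and T cells 10 against Control. OrdMag barcodes alone gave T cells 1 gene against ICB (Il1r2) and 9 against Control. Replicates 2 and 3 as separate samples gave neutrophils 4 against Control (Ankrd22, P2ry14, Relt and Scimp) and T cells 5 against ICB (Ccl3, Ccl4, Glp1r, Il1r2 and Tmtc4) and 31 against Control. Without each library in turn the counts ranged from 0 to 1 in fibroblasts for each comparison, from 0 to 3 and 0 to 1 in macrophages for ICB + CA-4948 against ICB and against Control, from 0 to 9, 0 to 4 and 0 to 10 in neutrophils, and from 0 to 11, 0 to 1 and 0 to 168 in T cells. The few genes named here were chosen after their values were seen.

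Lists called by camera numbered 0, 8 and 7 in malignant cells, 9, 6 and 12 in fibroblasts, 5, 5 and 6 in macrophages, 4, 5 and 2 in neutrophils and 9, 6 and 6 in T cells, for the comparisons in the same order. With an estimated correlation and by fry they were 0 in every class and comparison. With sex as a covariate there were 4 and 14 in malignant cells for ICB and for ICB + CA-4948 against Control, 10 and 19 in fibroblasts for ICB + CA-4948 against ICB and against Control, 10 in macrophages for ICB + CA-4948 against ICB, and 7 and 4 in neutrophils for ICB and for ICB + CA-4948 against Control. With the 2 components as separate samples there were 14 in malignant cells against Control, 2 and 7 in fibroblasts for ICB + CA-4948 against ICB and against Control, and 2 and 1 in neutrophils. With ambient counts subtracted there were 1 and 14 in malignant cells for ICB and for ICB + CA-4948 against Control, 2 in fibroblasts for ICB + CA-4948 against ICB, and 2 and 3 in macrophages for ICB and for ICB + CA-4948 against Control. Without each library in turn the number of lists ranged from 0 to 11 (ICB against Control) and 5 to 13 (ICB + CA-4948 against Control) in malignant cells, 3 to 9 (ICB + CA-4948 against ICB) and 6 to 14 (against Control) in fibroblasts, 5 to 9, 2 to 10 and 0 to 15 in macrophages in the order above, 1 to 10, 6 to 8 and 2 to 8 in neutrophils, and 1 to 12 (ICB against Control) and 2 to 9 (ICB + CA-4948 against Control) in T cells. The epithelial differentiation list of T cells, ICB against Control, reversed to 0.77 with ambient counts subtracted (adjusted p = 0.038), and the type I interferon list of fibroblasts ranged from -0.43 to 1.27 without each library.

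Whether the replicate numbers pair the samples is not known, and the deposit also carries sample numbers other than those of the titles, so the block may not follow the animals. Across genes, which are not independent replicates, the deviations of libraries with the same number from their group means correlated at 0.288 to 0.418 in fibroblasts, -0.07 to 0.205 in malignant cells, 0.03 to 0.251 in macrophages, -0.067 to 0.079 in neutrophils and -0.12 to 0.132 in T cells. All same-number pairs of fibroblasts were thus above 0, as were those of macrophages at lower values, and pairing stays open in both classes. Groups of 2 libraries have mirrored deviations, however, and these pairs are not independent. With the replicate number as a block, edgeR called 1 gene in fibroblasts for ICB + CA-4948 against ICB and 1 against Control (Ighg1 in both), 12 in macrophages against ICB, 5 and 5 in neutrophils for the same 2 comparisons, and 3, 18 and 76 in T cells. The 5 neutrophil genes included the Y-linked Ddx3y, Eif2s3y and Uty, with Gm14636, and AW011738 against ICB or P2ry14 against Control, and the 3 T cell genes were Krt18, Krt8 and Trbv14, all chosen after their values were seen. With this block camera called 8 and 12 lists in malignant cells for ICB and for ICB + CA-4948 against Control, 11 in fibroblasts for ICB + CA-4948 against ICB (6 without the block), 11 and 8 in macrophages for ICB against Control and ICB + CA-4948 against ICB, and 8 in neutrophils for ICB against Control.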

Other observations

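Macrophage states differed between libraries of 1 group; these shares were not tested for single libraries. A macrophage sub-cluster led by Cxcl3, a neutrophil-attracting chemokine, and Nos2, Inhba and Ptgs2, genes of inflammatory macrophages, made up 22.3% (95% Wilson interval 21 to 23.6%) of macrophages or monocytes in ICB replicate 3 and 13.6% (12.7 to 14.6%) in ICB + CA-4948 replicate 1, against at most 2.76% in the other libraries. A second one, led by Ch25h, Mmp13, Chil3 and Mgl2, genes that include marks of alternative activation, made up 20.5% (19.6 to 21.5%) in the merged ICB + CA-4948 library and 0.0371 to 7.26% elsewhere.

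A fibroblast state was concentrated in the first 2 of these tumours. A sub-cluster led by Nos2 and by Car9, Adm2 and Ero1a, genes of hypoxia and stress, made up 26.2% (22.8 to 29.9%) of fibroblasts in ICB replicate 3 and 23.2% (20.1 to 26.7%) in ICB + CA-4948 replicate 1, and 0.152 to 7.61% in the others. Inflammatory fibroblasts, which secrete cytokines such as Il6, made up 55.3% ± 24.3 (SD, n = 3) of fibroblasts in ICB and 49.7% ± 30.7 (n = 2) in Control, with single libraries from 15.3 to 82.3%. The fibroblast level of their gene list differed by replicate number. It was 7.19, 7.33 and 6.82 in replicate 1 of Control, ICB and ICB + CA-4948. It was 8.47 in Control replicate 2 and ICB replicate 2, 8.36 in the merged library and 7.66 in ICB replicate 3.

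In T and NK cells of Control replicate 1, a CD8 sub-cluster with Il31ra and ribosomal protein genes held 29.9% (27.3 to 32.7%) and an unnamed sub-cluster with Tox, Cd244a and Chn2 held 31.3% (28.7 to 34.1%), against at most 6.79 and 5.19% in the other libraries. Neutrophils of the ICB + CA-4948 libraries were unlike each other: Camp and Ngp, granule genes of immature neutrophils chosen after their values were seen, had log2 fold changes against ICB of 2.99 and 3.00 when ICB + CA-4948 replicate 1 was left out and of -5.60 and -5.02 when the merged library was left out. Control replicate 2 had 8.23 CPM of the Y-linked gene Ddx3y over all cells beside 334.5 CPM of Xist, where the other libraries with Xist had 0.03 to 0.76 CPM of Ddx3y.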
